A study of Homo sapiens with 30 samples.

How the data were processed

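RNA of HEK28 cells, of the parental HEK line and of 8 HEK28 knockout lines was purified with a column kit from cultures at about 70% confluency without treatment, and 3' RNA-seq libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, TopHat2, Bowtie and the genome build hg38, without versions or settings. The read counter, the gene annotation and the normalisation are not given in the sources used here. Each of the 30 samples was put in its group by its title and genotype label. For the LMAN1 knockout 1 genotype label is misspelled and the titles were used. The cell line label of the parental samples reads HEK28 as well, so their titles and genotype set the group.

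The deposited table holds log2 values, 16975 genes by 30 samples, with 5 significant digits. No header says how they were made, so their construction was read from the values. In 100% of them the linear value was a whole number of reads plus 0.5, within the rounding of 5 digits, divided by a length that belongs to the gene and by a size that belongs to the library. The reads were resolved for 16909 genes and not for 66. Lengths under 1000 came out within 0.1 of a whole number in 100% of 8690 genes, which fixes the length up to a common factor, and the scale of the values is known only up to a constant. A log2 value is therefore a level per unit of length, comparable between libraries for 1 gene. A value at 0 reads is set by the offset of 0.5 and by the depth of the library, and 8409 genes had 0 reads in at least 1 library. On simulated data 99.3% of the reads of 6000 genes were recovered. The smallest total of a listed gene was 18 reads, so genes with fewer reads are not listed, and 0 mitochondrially encoded genes were. Gene symbols are those of the table, and 21 of them had been turned into dates. Of the gene IDs 16938 were found in GENCODE 29 (GRCh38), which gave positions and gene types, and 37 were not. Reads shared with pseudogenes or paralogs, or with overlapping genes, cannot be told apart here.

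Replicates of a group differed beyond counting noise. The lowest chi-square per degree of freedom of a replicate pair was 1.52 over genes with at least 20 reads, so no pair was treated as 1 library, and Pearson's r of replicate pairs across genes ran from 0.882 to 0.968. Replicate numbers did not pair the samples, and the test has no block.

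The tests were fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with no further pseudocount since the values carry the offset of 0.5. A count model had been planned for a table of counts. The table holds normalised values, for which the plan named limma with a mean-variance trend and robust empirical Bayes moderation, and this was used. All 30 samples entered 1 model with 1 coefficient per group, so that the groups share 1 estimate of the spread. The 14 comparisons were each knockout against HEK28, HEK28 against the parental line, and 5 direct comparisons between knockouts of related genes. A gene was tested if at least 3 libraries had a CPM of 16.3 or more, worth 10 reads at the median depth, and if it had at least 15 reads in all, which left 11191 genes, 9961 of them protein-coding. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05.

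Simulated data with 100 genes changed by 2-fold and 100 by 4-fold were run through the same test. For GABARAPL2 knockout against HEK28 (10582 genes) 41% of the 2-fold and 98% of the 4-fold changes were recovered, with 14 unchanged genes called (9.15% of calls). For LMAN1 knockout against MCFD2 knockout (10576 genes) the shares were 40% and 96%, with 2 unchanged genes called (1.45%). Most 2-fold changes were missed, so a gene that did not pass is not shown to be unchanged. These rates need not hold for the uneven HEK28 group.

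Gene lists were tested with limma's camera at a preset correlation of 0.01. Of 34 lists of pathways, stress responses and cell type markers, the 30 with at least 5 tested members entered, which made 270 tests over the 9 comparisons with a wild type, adjusted together. Camera asks whether a list shifts against all other genes. A 0.5 shift simulated in 1 list (CANX, 11191 genes) gave adjusted p = 8.43e-13, with 0 others called, which is no test of correlated genes. Of the 23 list calls 2 held with a correlation estimated from the data: ATF4 targets in the CANX knockout and p53 targets in the CALR knockout. The fry test, which asks whether a list's genes move 1 way on balance and makes no comparison with other genes, was run beside it.

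The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each comparison with a wild type, the targeted gene, F8, and the 8 genes with the largest positive and the 8 with the largest negative change among those that passed, with a mean of at least 5 on the linear scale in the higher group, every library of a group above every library of the other, and a protein-coding gene symbol. It adds up to 4 members of each list that passed, by smallest adjusted p, the 3 genes with the largest change each way in the direct comparisons together with both targets, and 8 genes called in all knockouts. Of the genes so named, the text mainly prints those whose call held with each library left out. With the 30 libraries left out in turn, calls of named genes were lost in 6 of 26 for CANX, 6 of 35 for CALR, 18 of 28 for LMAN1, 5 of 30 for MCFD2, 13 of 21 for GABARAP, 8 of 17 for GABARAPL1, 1 of 24 for GABARAPL2, 10 of 24 for ATG7 and 0 of 36 for HEK28 against the parental line.

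Where a group had 0 reads of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 reads the ratio of reads per depth is given with its exact 95% interval. These intervals and floors cover counting error only, since reads were not counted by molecular identifiers. The alternatives were quantile normalisation, a fit without trend, no filter, a filter of CPM 2 in 3 libraries, the 6 samples of a comparison alone, a replicate block, pseudocounts of 0.1 and 5 added to the linear values, a 2-fold minimum, and each of the 30 libraries left out in turn. Chosen after the data were seen were the fit without HEK28 replicates 1 and 2, a pseudocount of 1 and voom weights from recovered reads. So were a filter at 10 reads in the shallowest library, list tests of CALR against CANX and the search along chromosomes. So was the test of each knockout against the mean of the other 7 (4 genes each way named by the same rule). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the recovery of reads and the positions.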

Results

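Messenger RNA was measured by 3' RNA-seq, which reads a short tag near the 3' end of each transcript, in a human cell line that makes coagulation factor VIII. HEK28 is, per the series' design text, a HEK293 (human embryonic kidney) line that secretes factor VIII, the product of F8. The design asks what loss of single genes does in these cells. The 10 groups of 3 samples each were HEK28 itself, the parental HEK line, and 8 HEK28 lines in each of which CRISPR had been aimed at CANX, CALR, LMAN1, MCFD2, GABARAP, GABARAPL1, GABARAPL2 or ATG7. CANX and CALR encode calnexin and calreticulin, lectin chaperones of the endoplasmic reticulum. LMAN1 and MCFD2 form the receptor that carries factor VIII out of that compartment. The GABARAP genes encode ATG8-family proteins of autophagosomes, and ATG7 encodes the enzyme that starts their attachment to lipid. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

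The deposited table held 16975 genes as log2 values per feature length and per library size, up to a constant. Reads in genes, recovered from the steps of the values, ran from 149946 in HEK28 replicate 1 to 3923295 in GABARAPL2 knockout replicate 1, with a median of 610626. The groups spanned 329081 to 2120832 reads (CANX knockout), 631018 to 2899301 (CALR knockout), 575068 to 3148869 (LMAN1 knockout) and 386377 to 1946447 (MCFD2 knockout). The ranges were 467062 to 1112688 for the GABARAP knockout, 429422 to 1179723 for GABARAPL1, 709506 to 3923295 for GABARAPL2, 243906 to 1175444 for ATG7 and 157365 to 608041 for the parental line. HEK28 replicates 1, 2 and 3 held 149946, 410049 and 302523 reads, and 5068, 2933 and 3195 of the listed genes had 0 reads in them. Counting intervals and floors given below cover counting error only.

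HEK28 replicates 1 and 2 lacked transcripts that the rest of the series contained. Of the transcripts for which the knockout libraries predicted at least 10 reads, 106 of 3687 (2.87%) had less than 10% of them in replicate 1 and 248 of 7136 (3.48%) in replicate 2, against 7 of 5941 (0.118%) in replicate 3. Among knockout libraries the share ran from 0.0309% to 0.533%, apart from LMAN1 knockout replicate 2 at 0.959%, and in the parental libraries from 1.12% to 1.69%. NOP10, a component of small nucleolar ribonucleoproteins, is an example, with log2 values of 1.34 and 0.02 in HEK28 replicates 1 and 2, 7.15 in replicate 3 and 6.67 ± 0.71 (SD, n = 24) over the knockout libraries. The first principal component, 20.61% of the variance, put HEK28 replicates 1 and 2 at 85.98 and 97.82 and replicate 3 at -13.99. The third, 6.97%, put replicate 3 at -32.71, below every other library, and replicates 1 and 2 at -3.03 and -3.72. Every comparison with HEK28 was therefore also run without replicates 1 and 2, a setting chosen after the data were seen, which rests on replicate 3 alone and assumes that it varies like the libraries of the other groups.

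**Figure D1:**
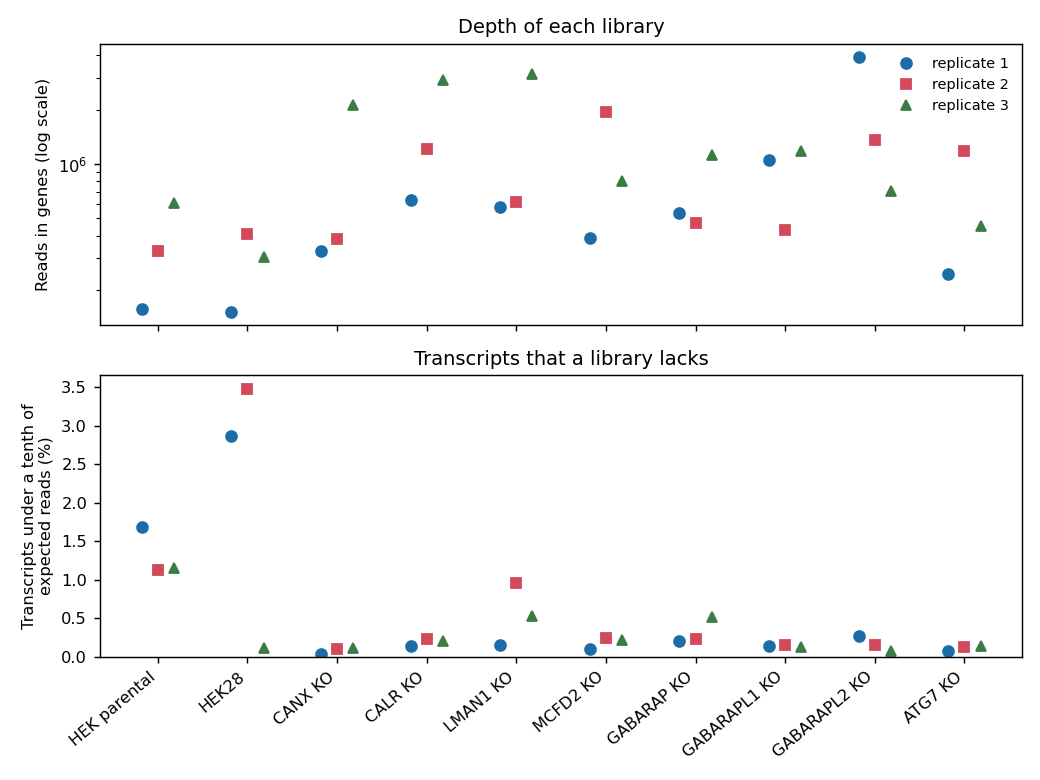
Reads in genes on a log scale (upper panel) and the percentage of well-expressed transcripts with less than 10% of their expected reads (lower panel), with 1 point per library for the 10 groups. HEK28 replicates 1 and 2 lie at 2.87% and 3.48% in the lower panel, above all other libraries, and replicate 3 at 0.118%.

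The transcript of the targeted gene was lower than in HEK28 in the knockouts of CANX, CALR, LMAN1 and MCFD2, and did not pass the test in those of GABARAP, GABARAPL1, GABARAPL2 and ATG7. Calnexin transcripts (CANX, ENSG00000127022, chromosome 5, 179678628 to 179730925, GRCh38) stood at 8.65 ± 0.05 in the knockout and 9.86 ± 0.15 in HEK28 (log2, SD, n = 3), a log2 fold change of -1.21 (adjusted p = 2.24e-05). CANX lies in a stretch of chromosome 5 in which 26 of 32 tested genes were lower in this knockout, with a median of -0.85 against the other 7 knockouts, where CANX itself differed by -1.15, so its fall is in large part shared with its neighbours. CALR (ENSG00000179218, chromosome 19, 12938578 to 12944489) went from 7.18 ± 0.40 to 3.92 ± 0.39, a change of -3.25 (adjusted p = 5.79e-08), and against the other 7 knockouts by -2.49, in a stretch of chromosome 19 with a median of -0.41. LMAN1 (ENSG00000074695, chromosome 18, 59327823 to 59359962) went from 7.21 ± 0.69 to 4.38 ± 0.46, a change of -2.83 (adjusted p = 7.9e-07). In these 3 knockouts all 3 libraries lay below all 3 HEK28 libraries. MCFD2 (ENSG00000180398, chromosome 2, 46901870 to 46941855) measured 7.24 ± 0.36 against 8.12 ± 0.91, a change of -0.88 (adjusted p = 0.0317), with HEK28 replicate 1 inside the range of the knockout. That last call ended without MCFD2 knockout replicate 2 (adjusted p = 0.0579) or 3 (0.135), without HEK28 replicate 2 (0.0964) or 3 (0.166) and with voom weights (0.0501). Without HEK28 replicates 1 and 2 the MCFD2 change was -1.72 (adjusted p = 0.000402), and against the other 7 knockouts it was -1.54 (adjusted p = 0.000117).

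The remaining targets carried few reads. GABARAP (ENSG00000170296, chromosome 17, 7240014 to 7242770) had 29 reads in its knockout and 36 in HEK28, with a log2 fold change of -1.07 (adjusted p = 0.161). GABARAPL1 (ENSG00000139112, chromosome 12, 10212458 to 10223130) had 48 and 19 reads and a change of -0.48 (adjusted p = 0.473). ATG7 (ENSG00000197548, chromosome 3, 11272309 to 11557665) had 12 and 8 reads and a change of -0.99 (adjusted p = 0.24). GABARAPL2 (ENSG00000034713, chromosome 16, 75566351 to 75577881) had 316 and 51 reads, at 6.28 ± 0.46 in its knockout and 5.94 ± 1.62 in HEK28 (SD, n = 3), a change of 0.34 (adjusted p = 0.63). The GABARAPL2 difference turned to -0.30 without HEK28 replicate 1, was 1.25 without replicate 3 (adjusted p = 0.0056) and -1.48 without replicates 1 and 2 (adjusted p = 0.0553). GABARAP passed without HEK28 replicate 3 (-1.48, adjusted p = 0.0283) and went to -0.25 without replicates 1 and 2 (0.887). In that last fit ATG7 turned to 0.09 and GABARAPL1 was at -1.05 (adjusted p = 0.974 and 0.424). Against the other 7 knockouts the differences were -0.51 for GABARAP, -1.20 for GABARAPL1, -0.73 for GABARAPL2 and -1.16 for ATG7 (adjusted p = 0.483, 0.0994, 0.29 and 0.193). With voom weights GABARAPL1 and GABARAPL2 passed in that comparison (adjusted p = 0.034 and 0.0267), and GABARAP and ATG7 did not (0.288 and 0.435). A frameshift made by CRISPR need not lower the transcript, and a 3' tag outside the edited part does not read the edit, so these 4 values do not check the labels.

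**Figure D2:**
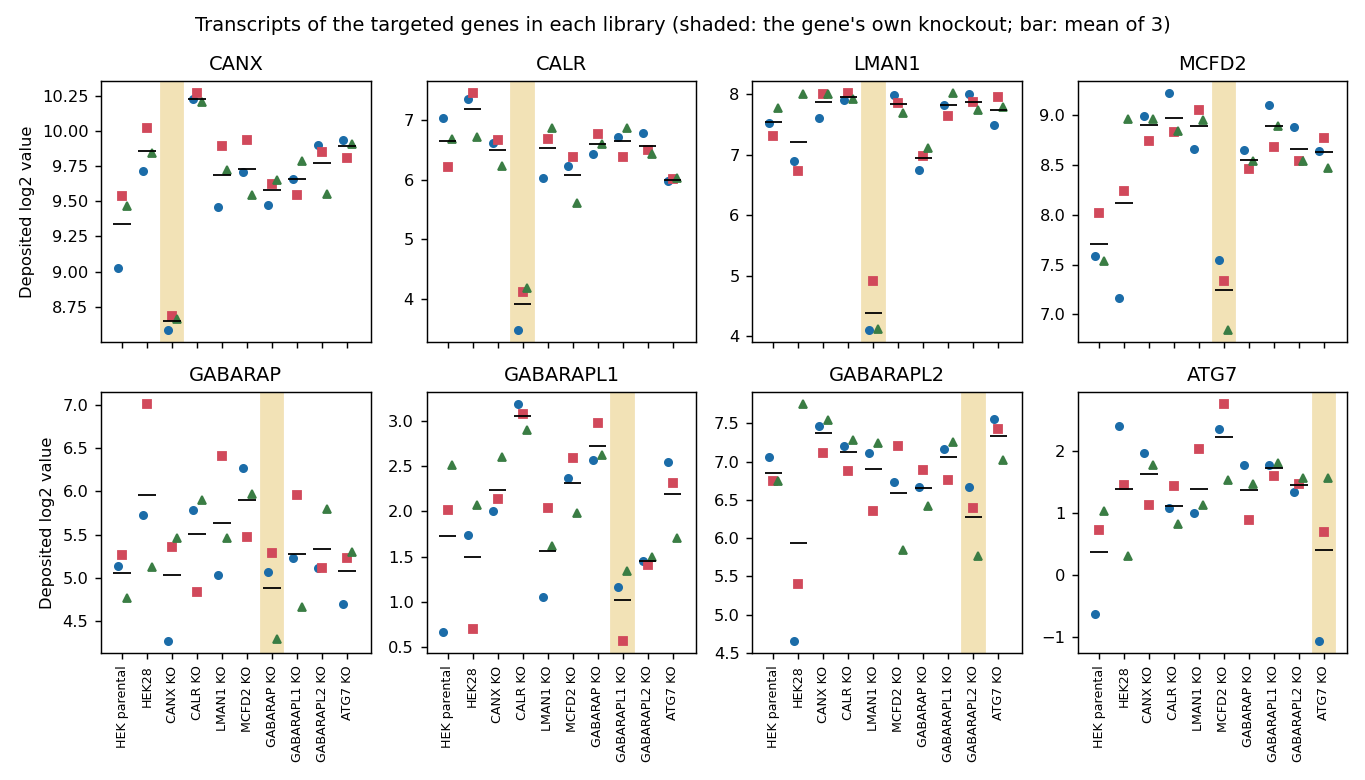
Deposited log2 value of the 8 targeted genes in each library, with the gene's own knockout shaded, circles, squares and triangles for replicates 1, 2 and 3 and a bar at the mean of 3. CANX, CALR and LMAN1 lie lowest in their own knockouts, at means of 8.65, 3.92 and 4.38, and the vertical axes start above 0 and differ between panels.

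F8 (ENSG00000185010, chromosome X, 154835788 to 155026940), which encodes factor VIII, was high in HEK28 and in all 8 knockouts and nearly absent from the parental line. It had 592 reads in the HEK28 libraries and 2 in the parental ones, a ratio of 417 (95% counting interval 115 to 3450), and means of 8.29 ± 0.25 and 0.09 ± 0.76 (log2, SD, n = 3; adjusted p = 1.88e-18). All 24 knockout libraries lay above all 3 HEK28 libraries. The rise over HEK28 passed the test in 5 knockouts. It was 2.86-fold with CALR targeted (adjusted p = 8.84e-05), 2.25-fold with GABARAPL1 (0.00513) and 2.07-fold with MCFD2 (0.00274). It was 1.86-fold with GABARAP (0.0229) and 1.81-fold with CANX (0.0119). With LMAN1, GABARAPL2 and ATG7 targeted F8 was at 1.66, 1.43 and 1.48 times the HEK28 level (adjusted p = 0.0529, 0.0873 and 0.096). Without HEK28 replicates 1 and 2, which leaves 1 HEK28 library, the log2 fold change was smaller, at 1.31 for CALR and 0.65 for CANX. It was 0.84 for MCFD2, 0.69 for GABARAP and 0.96 for GABARAPL1. With 1 HEK28 library this fit cannot show that the 5 rises hold. With the 6 samples alone all 5 calls ended (lowest adjusted p = 0.0635).

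The call for F8 in the CANX knockout also ended without HEK28 replicate 2 (adjusted p = 0.07). The call in the GABARAP knockout ended without GABARAP knockout replicate 1, 2 or 3 (0.0622, 0.0788 and 0.0584) or HEK28 replicate 1 or 2 (0.0609 and 0.0982). F8 passed in the LMAN1, GABARAPL2 and ATG7 knockouts too without HEK28 replicate 3 (adjusted p = 0.0161, 0.0486 and 0.0457). With voom weights it passed in all 8 knockouts, where the highest adjusted p was 0.0114. Set against the other 7 knockouts, F8 was higher in the CALR knockout by 0.69 (adjusted p = 0.0248) and passed in no other. No direct comparison between knockouts passed for F8 in the main limma fit. The differences were -0.27 between the GABARAP and GABARAPL1 knockouts, 0.38 between GABARAP and GABARAPL2 and 0.65 between GABARAPL1 and GABARAPL2 (adjusted p = 0.886, 0.33 and 0.158). They were -0.31 between LMAN1 and MCFD2 and 0.66 between CALR and CANX (adjusted p = 0.499 and 0.184). The last 4 of these passed with voom weights (adjusted p = 0.00858, 1.57e-05, 0.0233 and 4.33e-06). Those of 0.38, 0.65 and 0.66 passed with the 6 samples alone (0.0139 to 0.0392). These are transcript levels, and secreted factor VIII was not part of the table.

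**Figure D3:**
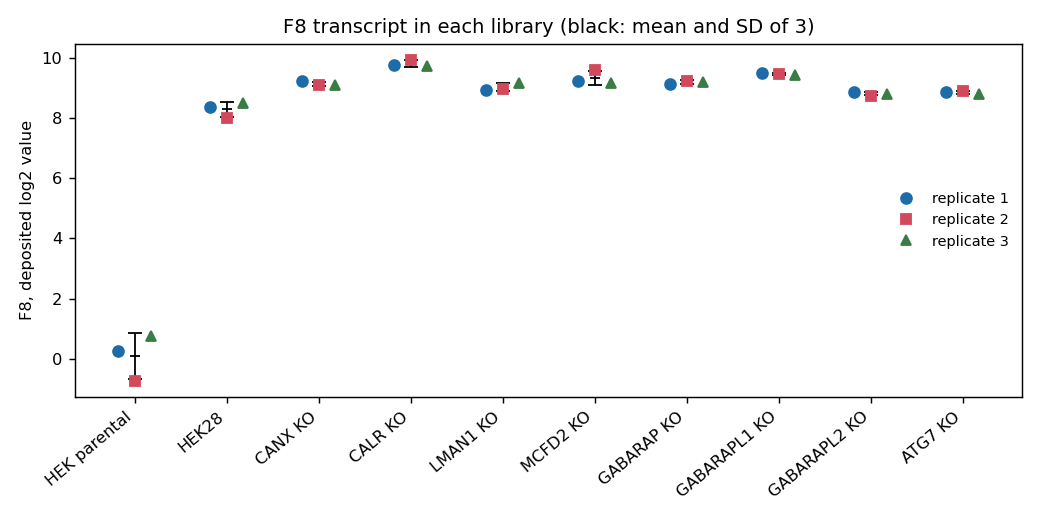
F8 transcript (deposited log2 value) in each library of the 10 groups, with the mean and SD of 3 in black. The parental libraries lie near 0, the HEK28 libraries around 8.29, and all knockout libraries above them, up to a mean of 9.81 in the CALR knockout.

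HEK28 differed from the parental line beyond F8. The lactate dehydrogenase genes LDHB (log2 fold change 1.71, adjusted p = 6.36e-09) and LDHA (2.35, adjusted p = 1.28e-08) rose, with 13 of 21 tested glycolysis genes higher and 5 lower (list adjusted p = 0.276 with an estimated correlation). ATP5G1, a subunit of mitochondrial ATP synthase, rose by 2.18 (adjusted p = 7.72e-11), with 31 of 78 oxidative phosphorylation genes higher and 7 lower (list adjusted p = 0.695 with an estimated correlation). Ribosomal protein genes rose in 30 of 67 cases and fell in 7, with RPL12 at 2.65 and RPL3 at 2.12 (adjusted p = 4.67e-12 and 8.93e-12; list adjusted p = 0.695 with an estimated correlation). Genes of G2 and mitosis rose in 15 of 25 cases and fell in 1, with cyclin B1 (CCNB1) at 1.96 (adjusted p = 1.96e-07; list adjusted p = 0.276 with an estimated correlation). Immediate early genes were lower, 6 of 13 with 0 higher, among them EGR1 (-3.79, adjusted p = 4.25e-09) and IER2 (-3.18, adjusted p = 1.69e-09; list adjusted p = 0.0807 with an estimated correlation). GSTZ1, an enzyme of tyrosine breakdown, had 79 reads in HEK28 and 0 in the parental line, at least 37.1-fold higher (adjusted p = 1.19e-08). Lower in HEK28 were NFKBIA, the inhibitor of NF-kB, at 5.35 ± 2.60 against 11.42 ± 0.05 (SD, n = 3; adjusted p = 2.47e-07), and the P-TEFb inhibitor HEXIM1 (-4.48, adjusted p = 2.78e-10). SERTAD1 had 2 against 140 reads, a ratio of 49.7 (95% counting interval 13.5 to 414). In each of these genes all 3 libraries of a group lay above all 3 of the other.

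With limma, 1896 genes were higher and 1699 lower in HEK28 than in the parental line at an adjusted p under 0.05, out of 11191 tested, 2742 of them by 2-fold or more. Without HEK28 replicates 1 and 2 the count was 2476, of which 1613 were shared in the same direction. Quantile normalisation gave 1914 higher and 1576 lower, voom weights 2325 genes and the 6 samples alone 542. The camera list tests gave adjusted p = 0.00142 for glycolysis (adjusted p = 0.276 with an estimated correlation) and 0.002 for oxidative phosphorylation (adjusted p = 0.695 with an estimated correlation). They gave 4.55e-05 for ribosomal proteins (0.695), 0.000106 for G2 and mitosis (0.276) and 0.000106 for immediate early genes (0.0807), with the adjusted p for an estimated correlation in brackets. Adjusted over the list alone, 13 glycolysis genes were higher and 5 lower, and 34 and 9 of oxidative phosphorylation. The same counts were 30 and 7 for ribosomal proteins, 16 and 1 for G2 and mitosis and 0 and 8 for immediate early genes. The oxidative phosphorylation and ribosomal calls ended without HEK28 replicate 3 (adjusted p = 0.436 and 0.177), and all 5 passed without replicates 1 and 2.

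The 8 knockouts were each set against HEK28. In the genes named below with an adjusted p, all 3 knockout libraries lay above, or all 3 below, the HEK28 libraries, and the 8 comparisons share the same HEK28 libraries. The tests draw on a spread estimated over all 30 libraries: with only the 6 samples of a comparison at most 33 genes passed in any of the 8, and 63 of the 275 calls of named genes in all comparisons held. Quantile normalisation shifted the median log2 fold change of all genes by -0.20 in the CANX, -0.21 in the CALR, -0.16 in the LMAN1, and -0.18 in the MCFD2 comparison. The shift was -0.14 in the GABARAP, -0.19 in the GABARAPL1, -0.27 in the GABARAPL2 and -0.16 in the ATG7 comparison. The balance of higher and lower genes depends on the scaling and is given both ways. The direction of every list named as called below held under that normalisation.

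CANX targeting went with a rise of ATF4 targets, genes of amino acid supply and the integrated stress response. In the CANX knockout 17 of 33 tested ATF4 targets rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.23. They included asparagine synthetase, ASNS, at 10.03 ± 0.25 against 8.25 ± 0.55 (SD, n = 3; adjusted p = 0.000391). Others were the serine synthesis gene PSAT1 (2.81, adjusted p = 0.000599), stanniocalcin 2 (STC2, 2.38, adjusted p = 0.000437) and the mTORC1 inhibitor DDIT4 (2.62, adjusted p = 0.000895). Hypoxia and HIF targets rose in 8 of 16 cases and fell in 0 (9 and 0 adjusted over the list alone), among them the mitophagy receptor BNIP3L (1.88, adjusted p = 0.00082). That list gave adjusted p = 0.0135, or adjusted p = 0.481 with an estimated correlation and 0.102 without HEK28 replicates 1 and 2. CD4, known as a T cell co-receptor, had 139 reads in the knockout and 0 in HEK28, at least 14.4-fold higher (adjusted p = 1.39e-05). SWAP70, an actin-binding signalling protein, fell from 3.47 ± 0.46 to 0.29 ± 0.90 (SD, n = 3; adjusted p = 4.28e-05), and the translation factor subunit EEF1D fell by 3.11 (adjusted p = 0.000272). CD4 and SWAP70 passed again without HEK28 replicates 1 and 2, and the genes named above from the ATF4 and hypoxia lists and EEF1D did not.

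The ATF4 list passed camera at adjusted p = 1.72e-07 (adjusted p = 0.0169 with an estimated correlation, 3.08e-08 without HEK28 replicates 1 and 2). In all, 1405 genes were higher and 731 lower with CANX targeted (1000 and 1050 under quantile normalisation), and 1 gene passed with the 6 samples alone. Leaving out CANX knockout replicate 1, 2 or 3 left 1316, 1379 and 1239 genes, and leaving out HEK28 replicate 1, 2 or 3 left 941, 946 and 3809. The number was 327 without HEK28 replicates 1 and 2, and 170 of these genes were shared.

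In the CALR knockout the lists of p53 targets and of hypoxia and HIF targets passed. The adjusted p was 0.000218 for p53 targets (adjusted p = 0.0169 with an estimated correlation) and 0.000331 for hypoxia (adjusted p = 0.209 with an estimated correlation). Of 16 tested hypoxia genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), among them BNIP3L (log2 fold change 2.65, adjusted p = 1.25e-05), PDK1, the kinase that restrains pyruvate dehydrogenase (3.77, adjusted p = 3.59e-05), and NDRG1 (1.81, adjusted p = 9.83e-05). Of 16 p53 targets 8 rose and 0 fell (9 and 0 adjusted over the list alone), such as MDM2, which turns p53 over. MDM2 stood at 12.04 ± 0.19 against 10.69 ± 0.47, and the cell cycle inhibitor CDKN1A at 4.96 ± 0.10 against 2.81 ± 0.30 (SD, n = 3; adjusted p = 3.03e-05 for each). Optineurin (OPTN), an autophagy receptor, rose by 3.26 (adjusted p = 2.63e-06). It was among 6 of 19 autophagy receptor and cargo genes that rose, with 0 lower (6 and 0 adjusted over the list alone; list adjusted p = 0.044, or adjusted p = 0.481 with an estimated correlation). The adhesion protein gene MXRA8 stood at 9.11 ± 0.27 against 5.11 ± 0.28 (SD, n = 3; adjusted p = 7.87e-06). STMN2, a microtubule regulator of neurons, had 0 reads against 10 in HEK28, at least 18.2-fold lower (adjusted p = 0.000312), and HSPBP1, an Hsp70 co-chaperone, fell by 2.67 (adjusted p = 7.68e-05). These genes all passed again without HEK28 replicates 1 and 2.

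Ribosomal protein genes in the CALR knockout rose in 34 of 67 cases and fell in 6 (40 and 9 adjusted over the list alone), a list at 5.79e-05 (adjusted p = 0.695 with an estimated correlation). Extracellular matrix and adhesion genes rose in 7 of 25 with 0 lower (7 and 0 adjusted over the list alone), a list at 0.0199 (adjusted p = 0.47 with an estimated correlation). With HEK28 replicates 1 and 2 left out the hypoxia and p53 lists passed (0.00657 and 3.36e-05), and those of autophagy receptors, ribosomal proteins and matrix genes did not (0.285, 0.518 and 0.211). The autophagy receptor call was lost without CALR knockout replicate 3 (adjusted p = 0.0527), HEK28 replicate 2 (0.226) or 3 (0.0695), or LMAN1 knockout replicate 1 (0.0505). It was also lost without ATG7 knockout replicate 3 (0.0541), parental replicate 2 (0.0503) or 3 (0.0507), and with the replicate number as a block (0.0502). Matrix genes lost theirs without HEK28 replicate 1 (0.0707) or 3 (0.062). Of all genes 1356 were higher and 700 lower (976 and 1022 under quantile normalisation), and with the 6 samples alone 1 passed. The totals were 1256, 1330 and 1233 without CALR knockout replicate 1, 2 or 3, and 1197, 1195 and 3532 without HEK28 replicate 1, 2 or 3. They came to 607 without HEK28 replicates 1 and 2, 335 of them shared.

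With LMAN1 targeted the lists of ribosomal proteins, oxidative phosphorylation and p53 targets passed. Their adjusted p was 9.13e-12, 0.000429 and 0.00998 (adjusted p = 0.565, 0.695 and 0.0819 with an estimated correlation). Without HEK28 replicates 1 and 2 the median went from 0.50 to 0.11 for ribosomal proteins (adjusted p = 0.0861) and from 0.53 to -0.07 for oxidative phosphorylation (0.521), and the p53 list passed (0.00657). Of 67 ribosomal protein genes 31 rose and 0 fell (44 and 1 adjusted over the list alone), led by RPL6 at 14.68 ± 0.11 against 13.78 ± 0.15 (SD, n = 3; adjusted p = 1.27e-05). Of 78 oxidative phosphorylation genes 15 rose and 0 fell (28 and 1 adjusted over the list alone). Among p53 targets 5 of 16 rose and 0 fell (5 and 0 adjusted over the list alone), with MDM2 up by 0.97 (adjusted p = 0.00506). PPP1R14C, which encodes an inhibitor of protein phosphatase 1, had 129 reads against 1, a ratio of 27.9 (95% counting interval 4.93 to 1110; adjusted p = 9.42e-06). The zinc finger gene ZNF616 had 77 against 0, at least 5.56-fold higher (adjusted p = 0.000116). SWAP70 fell by 2.71 (adjusted p = 0.000675) and the actin-severing scinderin gene SCIN by 3.23 (adjusted p = 0.000694). RPL6, PPP1R14C, ZNF616 and SWAP70 passed again without HEK28 replicates 1 and 2.

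The call for the p53 targets was lost without LMAN1 knockout replicate 2 (adjusted p = 0.087) or HEK28 replicate 3 (0.117). With LMAN1 targeted 509 genes were higher and 106 lower (250 and 136 under quantile normalisation), and 0 passed with the 6 samples alone. LMAN1 knockout replicate 2 stood apart from replicates 1 and 3, at 37.28 against -21.97 and -26.25 on the first principal component. The total was 50, 1020 and 99 genes without LMAN1 knockout replicate 1, 2 or 3, and 155, 171 and 2701 without HEK28 replicate 1, 2 or 3. It was 145 without HEK28 replicates 1 and 2, 39 of them shared.

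With MCFD2 targeted the lists of hypoxia genes, p53 targets and matrix genes passed, at 0.00199, 0.0104 and 0.0055 (adjusted p = 0.276, 0.0819 and 0.276 with an estimated correlation). They gave 0.028, 0.00413 and 0.091 without HEK28 replicates 1 and 2. BNIP3L and NDRG1 rose by 2.73 and 1.81 (adjusted p = 9.9e-06 and 0.000112), with 7 of 16 hypoxia genes higher and 0 lower (8 and 0 adjusted over the list alone). The p53-induced cell death gene BBC3 rose by 2.59 (adjusted p = 2.01e-05), with 5 of 16 p53 targets higher and 0 lower (6 and 1 adjusted over the list alone). The proteoglycan versican (VCAN) rose by 1.45 (adjusted p = 0.000729), with 7 of 25 matrix and adhesion genes higher and 0 lower (10 and 0 adjusted over the list alone). Optineurin stood at 9.08 ± 0.22 against 5.52 ± 0.60, and CD70, a ligand of the tumour necrosis factor family, at 7.04 ± 0.07 against 3.07 ± 1.03 (SD, n = 3; adjusted p = 2.82e-06 and 1.02e-05). The secreted glycoprotein STC1 had 105 reads against 0, at least 9.45-fold higher. The matrix protease MMP2 had 79 against 0, at least 7.11-fold higher (adjusted p = 0.00038). MNS1 fell by 3.02 (adjusted p = 0.000936). All genes named in this paragraph passed again without HEK28 replicates 1 and 2.

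The p53 list lost its call without HEK28 replicate 3 (adjusted p = 0.0802). With MCFD2 targeted 1198 genes were higher and 848 lower (948 and 1074 under quantile normalisation), and 0 passed with the 6 samples alone. The total was 1176 without MCFD2 knockout replicate 1, and 1189, 1162 and 3541 without HEK28 replicate 1, 2 or 3. It came to 644 without HEK28 replicates 1 and 2, 351 of them shared.

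GABARAP targeting left 1 tested list past the threshold, the ribosomal proteins, with 10 of 67 genes higher and 2 lower (29 and 6 adjusted over the list alone), such as RPL26 at a log2 fold change of 0.85 (adjusted p = 0.00604). The list stood at adjusted p = 0.0329, or adjusted p = 0.802 with an estimated correlation, and its median turned from 0.27 to -0.09 without HEK28 replicates 1 and 2 (adjusted p = 0.0613). The matricellular protein gene NOV (CCN3) fell from 7.52 ± 0.62 to 4.97 ± 0.40 (SD, n = 3; adjusted p = 1.57e-06). The calcium release channel RYR2 was at 4.97 ± 0.11 against 1.15 ± 1.39 (SD, n = 3; adjusted p = 0.00267). ZNF616 had 37 reads against 0, at least 5.05-fold higher (adjusted p = 0.000113). These 3 passed again without HEK28 replicates 1 and 2, and SCIN, which fell by 2.69 (adjusted p = 0.00315), did not. The ribosomal call was lost without GABARAP knockout replicate 2 (0.137), HEK28 replicate 1 (0.371) or 2 (0.16), and with fry (0.0629). Totals were 457 genes higher and 187 lower (341 and 242 under quantile normalisation), 242 genes with voom weights and 0 with the 6 samples alone. They were 142, 146 and 338 in sum without GABARAP knockout replicate 1, 2 or 3, and 194, 280 and 2447 without HEK28 replicate 1, 2 or 3. The sum was 292 without HEK28 replicates 1 and 2, 73 of them shared.

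In the GABARAPL1 knockout, RPL22L1, a paralog of the ribosomal protein gene RPL22, stood at 5.23 ± 0.36 against 2.08 ± 1.31 (SD, n = 3; adjusted p = 0.000214), and ZNF616 had 43 reads against 0, at least 4.69-fold higher (adjusted p = 0.000214). Both passed again without HEK28 replicates 1 and 2. RHBDF1 had 0 reads against 9, at least 9.17-fold lower (adjusted p = 0.0102), a call lost without GABARAPL1 knockout replicate 3 (0.0513) or HEK28 replicate 2 (0.066), with voom weights (0.0581) and with a pseudocount of 5 (0.0724). With camera 0 of the 30 lists passed, 5 had an unadjusted p under 0.05, and 12 passed with fry. The lowest camera adjusted p was that of the lysosome genes (0.0996), of which 6 of 34 rose and 0 fell with a median of 0.48. There were 809 genes higher and 324 lower (581 and 493 under quantile normalisation), 743 genes with voom weights and 0 with the 6 samples alone. In sum 315, 617 and 296 passed without GABARAPL1 knockout replicate 1, 2 or 3, and 262, 298 and 3009 without HEK28 replicate 1, 2 or 3. There were 184 without HEK28 replicates 1 and 2, 55 of them shared.

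With GABARAPL2 targeted the oxidative phosphorylation and ribosomal protein lists passed at 0.00133 and 0.0464 (adjusted p = 0.695 and 0.814 with an estimated correlation). Neither passed without HEK28 replicates 1 and 2 (adjusted p = 0.799 and 0.559), where the medians went from 0.64 to 0.15 and from 0.41 to 0. SLC25A5, the ADP/ATP exchanger of the inner membrane, was at 12.26 ± 0.12 against 7.24 ± 4.10 (SD, n = 3; adjusted p = 0.0026). Of 78 oxidative phosphorylation genes 37 rose and 5 fell (41 and 5 adjusted over the list alone). Those that rose included the complex I subunits NDUFB3 (4.28, adjusted p = 0.000674) and NDUFB6 (3.24, adjusted p = 0.00076). Collagen VI chain COL6A3 stood at 12.73 ± 0.28 against 8.03 ± 1.27 (SD, n = 3; adjusted p = 0.000215). The BMP antagonist GREM1 had 454 reads against 2, a ratio of 34.9 (95% counting interval 9.6 to 289). Ribosomal protein genes rose in 33 of 67 cases and fell in 8 (37 and 10 adjusted over the list alone), with RPL6 at 14.62 ± 0.09 against 13.78 ± 0.15 (SD, n = 3; adjusted p = 2.06e-05). STMN2 had 0 reads against 10, at least 21.7-fold lower (adjusted p = 0.000324), and ANKRD16 fell by 2.58 (adjusted p = 0.000132). RPL6, STMN2 and ANKRD16 passed again without HEK28 replicates 1 and 2, and SLC25A5, NDUFB3, NDUFB6, COL6A3 and GREM1 did not.

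The call for ribosomal proteins with GABARAPL2 targeted was also lost with the replicate block (0.0624), and without HEK28 replicate 1 (0.242) or 2 (0.0841) or GABARAPL2 knockout replicate 1 (0.07). It ended at 0.05 to 0.0583 without most single libraries of the other groups. In total 2089 genes were higher and 873 lower (1435 and 1536 under quantile normalisation), the highest number of the 8 with all HEK28 libraries, and 33 genes passed with the 6 samples alone. The number was 1908 and 1902 without GABARAPL2 knockout replicate 1 or 2, 1669 and 1593 without HEK28 replicate 1 or 2, and 351 without both, 232 of them shared, fewer than for MCFD2 (644) and CALR (607).

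With ATG7 targeted, 4 of 13 immediate early genes rose and 0 fell (6 and 0 adjusted over the list alone), IER2 among them at a log2 fold change of 1.36 (adjusted p = 0.00258). The list gave 0.0104 (adjusted p = 0.276 with an estimated correlation, 0.147 without HEK28 replicates 1 and 2). Oxidative phosphorylation genes rose in 20 of 78 cases and fell in 3 (28 and 8 adjusted over the list alone), with the complex III gene CYC1 up by 2.05 (adjusted p = 0.00229) and ATP5G1, an ATP synthase subunit, down from 11.82 ± 0.32 to 11.08 ± 0.03 (SD, n = 3; adjusted p = 0.00358). This list gave 0.0329 (adjusted p = 0.786 with an estimated correlation), and its median turned from 0.40 to -0.13 without HEK28 replicates 1 and 2 (adjusted p = 0.237). PPP1R14C had 57 reads against 1, a ratio of 26.6 (95% counting interval 4.58 to 1070; adjusted p = 1.58e-05). ZNF616 had 33 against 0, at least 5.13-fold higher (adjusted p = 0.000112). GSTZ1 fell by 3.33 (adjusted p = 0.000696) and the histone gene HIST1H2BC by 2.80 (adjusted p = 0.0012), and GSTZ1 lies in a stretch of chromosome 14 that was lower against the other 7 knockouts (26 genes, median -0.36). Of these genes PPP1R14C and ZNF616 passed again without HEK28 replicates 1 and 2.

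The call for oxidative phosphorylation was lost without ATG7 knockout replicate 1 (0.0547) or 2 (0.0689) or HEK28 replicate 1 (0.243) or 2 (0.159). Higher were 947 genes and lower 486 (694 and 662 under quantile normalisation), against 697 genes with voom weights and 0 with the 6 samples alone. Together they were 719, 717 and 796 without ATG7 knockout replicate 1, 2 or 3, and 408, 518 and 3250 without HEK28 replicate 1, 2 or 3. There remained 250 without HEK28 replicates 1 and 2, 86 of them shared.

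Across the 8 knockouts, 133 genes were higher and 5 lower than in HEK28 in all of them. PPP1R14C (ENSG00000198729) and ZNF616 (ENSG00000204611) were low in all 3 HEK28 libraries. PPP1R14C stood at 4.36, 4.62 and 3.47 against 7.54 ± 0.72 (SD, n = 24) in the knockout libraries and 8.14 ± 0.56 (SD, n = 3) in the parental ones. ZNF616 stood at 0.08, -1.24 and -0.80 against 2.57 ± 0.44 and 2.65 ± 0.34. NOP10 and the signal recognition particle gene SRP9 were low in HEK28 replicates 1 and 2 and not in replicate 3, where SRP9 read 1.47, 0.14 and 6.08 against 6.02 ± 0.81 in the knockouts. Leaving out HEK28 replicates 1 and 2 gave 73 genes that passed in all 8, of which 9 were among the 138, PPP1R14C and ZNF616 included and NOP10 and SRP9 not. All 73 were higher in the knockouts, and in 5 of them replicates 1 and 2 also lay at least 1 below the knockouts, so most of the 73 rest on replicate 3. Leaving out LMAN1 knockout replicate 1, 2 or 3 left 21, 212 and 30 genes called in all 8, and leaving out GABARAPL1 knockout replicate 1 or 3 left 78 and 75. Leaving out GABARAP knockout replicate 1, 2 or 3 left 38, 38 and 81, and HEK28 replicate 1, 2 or 3 left 33, 41 and 1272.

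With all HEK28 libraries the CANX and GABARAPL2 knockouts shared 1082 genes higher and 362 lower, with 4 opposite. Independent lists would share 262 and 57. Simulated unchanged groups shared 0, but without the departure of HEK28 replicates 1 and 2, and so do not test it. CALR and MCFD2 shared 874 and 432, with 5 opposite, against 145 and 53. Without HEK28 replicate 1 the shared genes were 426 and 142 for the first pair and 456 and 223 for the second. Without replicate 3 they were 2124 and 879, and 1847 and 837. The correlation of fold changes across genes, which are not independent replicates, was 0.80 and 0.85 (simulated 0.5). With HEK28 replicate 3 alone, not simulated, it was 0.74 and 0.86. The covariance was 0.763 and 0.688 against a simulated 0.11. With 3 HEK28 libraries the controls could not be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls.

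A comparison of each knockout with the mean of the other 7 was added after the data were seen, in which HEK28 libraries enter through the estimate of the spread alone. Higher with CANX targeted were CD4, with 139 reads against 18 in the other 7 lines together, STMN2, with 110 against 83, and CHAC1, a glutathione-degrading enzyme and ATF4 target, with a log2 difference of 3.04 (adjusted p = 7.17e-09, 0.00026 and 7.57e-05). The autophagy receptor SQSTM1 (p62) was lower there, at 5.10 ± 0.79 (SD, n = 3) against 7.14 ± 0.33 (SD, n = 21; adjusted p = 1.26e-05). SQSTM1 (chromosome 5, 179806398 to 179838078) lies in the same stretch of chromosome 5 as CANX (177809407 to 181272307), where 26 of 32 tested genes were lower with a median of -0.85. In the CALR knockout MXRA8 was higher by 3.19 (adjusted p = 6.93e-06). ASNS was lower by -1.58 (adjusted p = 0.000103). PYROXD1, an oxidoreductase, was lower in the LMAN1 knockout by -2.12 (adjusted p = 0.00224), in a lower stretch of chromosome 12 (33 genes, median -0.36). In the MCFD2 knockout CD70 was higher by 2.07 (adjusted p = 0.0012), and MNS1 and the splicing cofactor RAVER1 were lower by -3.47 and -2.75 (adjusted p = 3.73e-05 and 0.000114), RAVER1 in a lower stretch of chromosome 19 (97 genes, median -0.43).

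GABARAP targeting went with lower TDRD3 (-2.69, adjusted p = 0.000138) and the adhesion protein gene NECTIN4 (-2.21, adjusted p = 0.000313), and TDRD3 lies in a stretch of chromosome 13 (26254104 to 114132611) that was lower in this knockout (145 of 168 genes, median -0.51). In the GABARAPL1 knockout NOV was higher by 1.80 and the minor spliceosome gene SNRNP25 lower by -1.95 (adjusted p = 2.99e-06 for each), and RHBDF1 had 0 reads against 240 in the other 7 lines (adjusted p = 6.7e-05). With GABARAPL2 targeted the GABA receptor subunit GABRA3 was higher, with 253 reads against 77 in the other 7 lines, and COL6A3 was higher by 3.85 (adjusted p = 3.31e-05 and 0.000142). Metallothionein MT1X and desmoplakin (DSP) were lower by -1.93 and -1.10 (adjusted p = 2.25e-05 and 1.93e-06). ATG7 targeting set apart CDKN1A, at 2.05 ± 0.48 (SD, n = 3) against 3.59 ± 0.75 (SD, n = 21; adjusted p = 0.000292), and the collagen COL27A1 (-1.64, adjusted p = 2.22e-05), both lower, COL27A1 in a lower stretch of chromosome 9 (25 genes, median -0.52). In each gene named from this comparison all 3 libraries lay outside the range of the other 21, and the call held with each of the 30 libraries left out and under quantile normalisation.

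The counts in this comparison were 61 genes higher and 104 lower for CANX, 166 and 166 for CALR, 70 and 47 for LMAN1, 185 and 385 for MCFD2, 92 and 218 for GABARAP, 15 and 25 for GABARAPL1, 293 and 175 for GABARAPL2 and 36 and 129 for ATG7. Quantile normalisation gave 78 and 120, 198 and 207, 14 and 28, 261 and 339, 114 and 203, 15 and 33, 286 and 355, and 53 and 129 in the same order. With voom weights the totals were 552, 1891, 704, 1825, 847, 173, 2863 and 205, again in that order. Leaving out a library of the knockout itself lowered the totals most: to 80 and 51 for CANX (without replicate 1 or 2), 53 and 21 for LMAN1 (1 or 2), 228 and 252 for MCFD2 (1 or 3) and 63 and 90 for ATG7 (1 or 3). Without replicate 1, 2 or 3 of the same knockout the totals were 97, 94 and 129 for CALR, 135, 122 and 114 for GABARAP, 10, 12 and 18 for GABARAPL1 and 116, 110 and 113 for GABARAPL2. Without HEK28 replicate 3, which enters through the shared estimate of the spread, they were 252 for CANX, 556 for CALR, 257 for LMAN1, 544 for GABARAP, 69 for GABARAPL1, 829 for GABARAPL2 and 285 for ATG7.

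**Figure D4:**
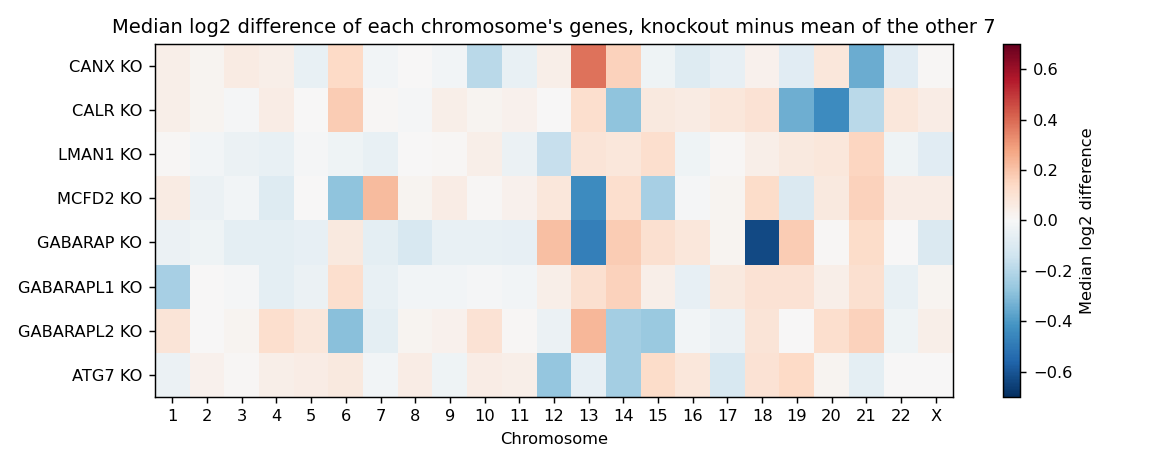
Median log2 difference of the tested genes of each chromosome, each knockout minus the mean of the other 7, on a colour scale from blue (lower) to red (higher). The lowest tiles are chromosomes 18 and 13 in the GABARAP knockout, at -0.63 and -0.48, and the highest is chromosome 13 in the CANX knockout, at 0.38.

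The direct comparisons set 1 knockout line against another, so loss of the gene and other line differences cannot be told apart. They use HEK28 libraries only in the estimate of the spread. In the order given here their counts were 94, 1260, 303, 885 and 242 without HEK28 replicate 3, and 108, 1429, 354, 1022 and 281 without replicates 1 and 2. Between the GABARAP and GABARAPL1 knockouts, NOV stood at 4.97 ± 0.40 against 8.24 ± 0.18 and RPL22L1 at 2.02 ± 0.33 against 5.23 ± 0.36 (SD, n = 3; adjusted p = 8.56e-09 and 0.000123), both lower with GABARAP targeted. BEX1 had 0 reads against 43, at least 11.5-fold lower (adjusted p = 0.000209). SNRNP25 was higher, at 6.76 ± 0.25 against 4.63 ± 0.29 (SD, n = 3; adjusted p = 6.39e-05). RHBDF1 had 17 reads against 0, at least 7.09-fold higher (adjusted p = 0.00545), a call that ended without GABARAP knockout replicate 1 (0.0511) and with a pseudocount of 5 (0.136). SNRNP25 and RHBDF1 lie at the end of chromosome 16 (46407 to 1686715), where 33 of 40 tested genes were lower in the GABARAPL1 knockout than in the other 7, with a median of -0.53. The targets themselves differed by -0.40 for GABARAP (adjusted p = 0.938) and 1.70 for GABARAPL1 (0.0574). With 8 genes higher and 42 lower (9 and 33 under quantile normalisation) this was the smallest of the 5 direct comparisons, and it gave 138 genes with voom weights and 8 with the 6 samples alone. It held 16, 16 and 19 genes without GABARAPL1 knockout replicate 1, 2 or 3 and 13, 32 and 23 without GABARAP knockout replicate 1, 2 or 3.

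The GABARAP and GABARAPL2 knockouts differed in STMN2, with 44 reads against 0, at least 39.1-fold higher with GABARAP targeted (adjusted p = 0.000227), and in GABRA3, with 0 against 253, at least 31.6-fold lower (adjusted p = 1.61e-05). The NADPH oxidase NOX1 had 2 reads against 339, a ratio of 63.6 to the lower side (95% counting interval 17.5 to 527; adjusted p = 0.00534). Neither target passed (GABARAP -0.46, adjusted p = 0.591; GABARAPL2 0.38, adjusted p = 0.681). There were 247 genes higher and 453 lower (462 and 421 under quantile normalisation, which shifted the median by 0.12), 2727 genes with voom weights and 2091 with the 6 samples alone. Without GABARAPL2 knockout replicate 1, 2 or 3 the totals were 276, 241 and 320, and without GABARAP knockout replicate 1, 2 or 3 they were 460, 362 and 305. Between the GABARAPL1 and GABARAPL2 knockouts, NOV stood at 8.24 ± 0.18 against 6.35 ± 0.22 and MT1X at 5.63 ± 0.29 against 3.47 ± 0.33 (SD, n = 3; adjusted p = 8.01e-05 and 0.000267). The targets differed by -0.43 for GABARAPL1 (adjusted p = 0.697) and 0.78 for GABARAPL2 (0.511). The test called 77 genes higher and 108 lower (137 and 116 under quantile normalisation), 1232 in sum with voom weights and 618 with the 6 samples alone. It called 51, 47 and 56 in sum without GABARAPL2 knockout replicate 1, 2 or 3 and 89, 55 and 107 without GABARAPL1 knockout replicate 1, 2 or 3.

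LMAN1 and MCFD2 act as a complex, and their knockouts differed in more than their own targets. LMAN1 was lower by -3.47 (adjusted p = 1.16e-08) and MCFD2 higher at 8.89 ± 0.20 against 7.24 ± 0.36 (SD, n = 3; adjusted p = 0.000858) with LMAN1 targeted. The transcription factor RUNX3 stood at 5.18 ± 0.61 against 1.36 ± 1.60 (SD, n = 3; adjusted p = 0.00147). With LMAN1 rather than MCFD2 targeted 395 genes were higher and 176 lower (291 and 201 under quantile normalisation), 1886 genes differed with voom weights and 1 with the 6 samples alone. The total was 312, 321 and 244 without LMAN1 knockout replicate 2, MCFD2 knockout replicate 1 and MCFD2 knockout replicate 3.

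CALR and CANX encode paralogous lectin chaperones, and the ATF4 targets parted their knockouts. Of 33 tested members 14 were higher with CANX targeted and 0 with CALR targeted (median CALR minus CANX -1.23). Camera, unplanned here, gave adjusted p = 1.24e-33 over 30 lists (1.64e-07 with an estimated correlation). CHAC1 stood at 0.40 ± 0.80 against 5.10 ± 0.36 (SD, n = 3; adjusted p = 7.35e-06). CD4 had 3 reads against 139, a ratio of 78.5 to the lower side in the CALR knockout (95% counting interval 26.3 to 385; adjusted p = 3.14e-07), and STMN2 0 against 110, at least 62.1-fold lower (adjusted p = 4.33e-05). Both targets were lower in their own knockouts, CANX together with its neighbours on chromosome 5: CALR was lower by -2.58 (adjusted p = 1.97e-06) and CANX stood at 10.23 ± 0.03 against 8.65 ± 0.05 (SD, n = 3; adjusted p = 3.14e-07). In all, 69 genes were higher and 78 lower (85 and 88 under quantile normalisation), and 776 differed with voom weights. There were 76 and 62 without CANX knockout replicate 1 or 2, and 57, 48 and 75 without CALR knockout replicate 1, 2 or 3.

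**Figure D5:**
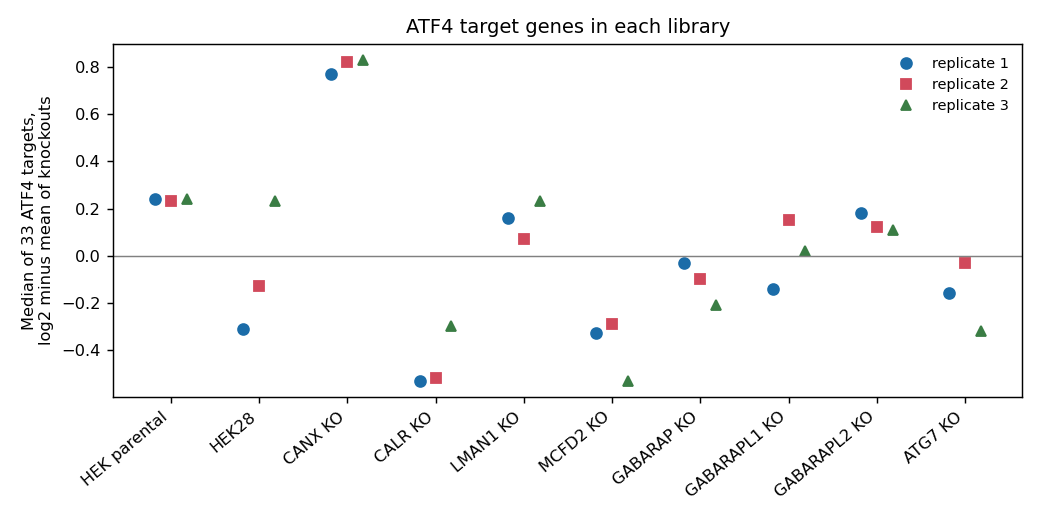
Median over 33 ATF4 targets of the deposited log2 value minus the mean of the 24 knockout libraries, with 1 point per library. The CANX knockout libraries lie at 0.77, 0.82 and 0.83 and the CALR knockout libraries at -0.53, -0.52 and -0.30, while HEK28 spreads from -0.31 to 0.23.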

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

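Tests of depth, GC content and mislabelling for transcripts lacking in HEK28 replicates 1 and 2 were chosen only after the result was seen. So were all values without those replicates and the ATF4 list tests of CALR against CANX. The sample splits were chosen before.

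Some genes went opposite ways from HEK28 in related knockouts, with each direction past the test and the direct difference past it too. Between the CALR and CANX knockouts these were asparagine synthetase (ASNS), the cystine transporter SLC7A11, CHAC1, which breaks down glutathione, and the long noncoding RNA RP11-256I9.2. ASNS lay at -1.25 with CALR targeted and 1.78 with CANX targeted, a direct difference of -3.03 (adjusted p = 4.03e-07). SLC7A11 gave -1.42, 0.96 and -2.39 (adjusted p = 9.7e-07), and CHAC1 -1.69, 3.01 and -4.70 (adjusted p = 7.35e-06). RP11-256I9.2, with 5 reads in the CALR and 357 in the CANX knockout, gave -4.42, 2.52 and -6.94 (adjusted p = 1.97e-06). Between the LMAN1 and MCFD2 knockouts they were the cytoskeletal linker plectin (PLEC) at -0.84, 0.98 and -1.81 (adjusted p = 7.32e-05), SLTM at 0.47, -0.46 and 0.93 (0.000143), and the ribosomal protein genes RPS27A at 0.42, -0.34 and 0.76 (0.000248) and RPS10 at 0.37, -0.30 and 0.68 (0.000378). RPS27AP16, a pseudogene that can share reads with RPS27A, gave 0.58, -0.49 and 1.07 (0.000423).

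The direct differences of all 9 genes passed with each of the 30 libraries left out, at most at an adjusted p of 0.00676, for RPS27AP16 without MCFD2 knockout replicate 3. Against HEK28 only ASNS and SLC7A11 kept both calls with each library left out. Without HEK28 replicate 1 each of the other 7 lost at least 1 of its calls against HEK28: CHAC1 (adjusted p = 0.111), RP11-256I9.2 (0.101), PLEC (0.171), SLTM (0.0821 and 0.0562), RPS27A (0.224), RPS10 (0.184) and RPS27AP16 (0.155 and 0.0819). Without HEK28 replicates 1 and 2 none of the 9 kept both; with CALR targeted ASNS, SLC7A11, CHAC1 and RP11-256I9.2 stayed lower than HEK28 (adjusted p = 0.00337, 0.0028, 0.00289 and 0.000386), while with CANX targeted they did not pass (0.0739, 0.316, 0.107 and 0.753). The 3 comparisons within the GABARAP family had 0 such genes, by the same limma tests.

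HEK28 replicates 1 and 2 lack transcripts that replicate 3 and the knockouts contain, and 54 transcripts were lacking in both against 2.56 if the losses were independent. Depth does not account for it: replicate 3 is shallower than replicate 2 and lacked 7 of 5941 transcripts (0.118%), against 248 of 7136 (3.48%). After the trend with the GC content of the 3' end was removed, 126 of 193 lacking transcripts of replicate 2 with a GC value stayed under 10% of their expected reads. Of the genes that set a knockout apart, at most 43.6% (LMAN1) lay nearer to it in replicate 3. In replicates 1 and 2 the share was at most 51.3% and 67.5% (LMAN1). The knockouts' own libraries, at 86.7% or more, helped to pick these genes and set no limit for a mislabelled one. A difference in culture, RNA or library preparation stays open, and so does a wrong label. That replicate 3 is odd in another way stays open too, as it lies lowest of all libraries on the third principal component (-32.71).

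ATF4 targets were higher with CANX than with CALR targeted. The HEK28 libraries that stand apart are not needed for it, as the direct comparison gave a camera adjusted p of 1.24e-33. Nor does depth account for it: the nearest libraries of the knockouts were 1.07 apart in the list median. Libraries of 1 knockout spanned at most 0.22. In the labels 0 knockouts have another line, so loss of the gene and other line differences cannot be told apart. That CANX targeting may raise these genes is a hypothesis, with no other line measured.

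With 3 samples against 3 there are 10 splits of the 6 libraries, which cannot give a share under 0.05. The real split and the highest other gave 2136 and 1355 genes for CANX, 2056 and 1136 for CALR, 615 and 2901 for LMAN1, 2046 and 1692 for MCFD2, 644 and 1229 for GABARAP, 1133 and 1617 for GABARAPL1, 2962 and 1130 for GABARAPL2, 1433 and 1303 for ATG7 and 3595 and 1136 for HEK28 against the parental line. In each knockout comparison the highest other split put HEK28 replicates 1 and 2 with 1 knockout library against HEK28 replicate 3 with the others, and in those of LMAN1, GABARAP and GABARAPL1 it called more genes than the real split (2 of 10 splits as large, the real one included), which points to a structure of the samples. The direct comparisons gave 50 and 0 (GABARAP and GABARAPL1), 700 and 0 (GABARAP and GABARAPL2), 185 and 0 (GABARAPL1 and GABARAPL2), 571 and 2 (LMAN1 and MCFD2) and 147 and 1 (CALR and CANX), with 1 split of 10 as large, the real one, in each.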

How the results depend on the processing

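The fits without HEK28 replicates 1 and 2, with a pseudocount of 1, with voom weights and with the filter at the shallowest library were chosen only after the result was seen; the others had been planned. The shallowest library, HEK28 replicate 1, held 149946 reads, and genes with few reads rest on the offset of 0.5. Counts below rose in some fits with fewer samples and fell in others, and why was not tested.

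Numbers below count genes at an adjusted p under 0.05. With 1 library of the 30 left out they ran from 941 to 3809 (CANX), 1195 to 3532 (CALR), 50 to 2701 (LMAN1), 1162 to 3541 (MCFD2), 142 to 2447 (GABARAP), 262 to 3009 (GABARAPL1), 1593 to 4381 (GABARAPL2), 408 to 3250 (ATG7) and 3017 to 4398 (HEK28 against parental). Each of these 9 was highest without HEK28 replicate 3, and lowest without HEK28 replicate 1 (CANX, GABARAPL1, ATG7, parental) or 2 (CALR, MCFD2, GABARAPL2), LMAN1 knockout replicate 1 or GABARAP knockout replicate 1. Direct comparisons ran from 13 to 32 (GABARAP and GABARAPL1), 241 to 460 (GABARAP and GABARAPL2), 47 to 107 (GABARAPL1 and GABARAPL2), 244 to 522 (LMAN1 and MCFD2) and 48 to 113 (CALR and CANX) without a library of the 2 groups compared, and up to 94, 1260, 303, 885 and 242 without HEK28 replicate 3. Genes called in all 8 knockouts ran from 21 to 1272, lists from 21 to 27, targets called lower from 3 to 4, and the F8 difference between HEK28 and the parental line from 7.79 to 8.53.

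Quantile normalisation moved LMAN1 to 386 and the genes called in all 8 to 91. With no filter, LMAN1 gave 360, GABARAP 394, GABARAPL1 751, ATG7 952, GABARAP against GABARAPL1 28 and all 8 knockouts 75. The CPM 2 filter, which is the laxer of the filters with 16971 genes, gave 360, 394, 753, 952, 28 and 75 for these and 54 lists called. The 6 samples alone gave 1 (CANX), 1 (CALR), 0 (LMAN1), 0 (MCFD2), 0 (GABARAP), 0 (GABARAPL1), 33 (GABARAPL2), 0 (ATG7), 542 (parental), 8 (GABARAP and GABARAPL1), 2091 (GABARAP and GABARAPL2), 618 (GABARAPL1 and GABARAPL2) and 1 (LMAN1 and MCFD2). A 2-fold minimum gave 120 for GABARAPL1 against GABARAPL2 and 308 for LMAN1 against MCFD2. A pseudocount of 5 gave 32 for GABARAP against GABARAPL1 and 320 for GABARAPL1 against GABARAPL2. Of 270 list tests 23 passed with the preset correlation, 2 with an estimated correlation and 127 with fry.

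The filter at the shallowest library, with 3746 genes, gave 1383 (CANX), 1361 (MCFD2), 1664 (GABARAPL2) and 1901 (parental), and no value for targets it removed. Voom weights gave 242 (GABARAP), 743 (GABARAPL1), 697 (ATG7), 2325 (parental), 53 in all 8, and in the direct comparisons 138, 2727, 1232, 1886 and 776, in the order above. Without HEK28 replicates 1 and 2 the counts were 327 (CANX), 607 (CALR), 145 (LMAN1), 644 (MCFD2), 292 (GABARAP), 184 (GABARAPL1), 351 (GABARAPL2), 250 (ATG7) and 73 in all 8, with 108, 1429, 354, 1022 and 281 in the direct comparisons. In that fit GABARAPL2 turned to -1.48 in its own knockout (-0.30 without HEK28 replicate 1, 1.25 without replicate 3) and ATG7 to 0.09 in its own, and the medians of 4 lists turned: oxidative phosphorylation to -0.07 (LMAN1) and -0.13 (ATG7), ribosomal proteins to -0.09 (GABARAP) and 0 (GABARAPL2).

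Replicate numbers did not pair the samples. In no comparison did all 3 pairs correlate over 0.1 in their deviations, and 12 of 30 libraries correlated best with a library of their own number. With the replicate block the counts were 2094, 2024, 603, 2022, 605, 1117, 2928 and 1417 for the knockouts in the order above, 3554 for the parental line, 39, 690, 166, 558 and 140 for the direct comparisons, 136 in all 8 and 21 lists, with 4 targets called and F8 at 8.20. Of 275 calls of named genes, 272 held with the block, 272 under quantile normalisation, 271 without trend, 263 with no filter or CPM 2, 269 and 275 with pseudocounts of 5 and 0.1, 274 with 1, 106 of 106 with the filter at the shallowest library, 235 with voom weights, 63 with 6 samples and 125 without HEK28 replicates 1 and 2. The list calls kept of 23 were 23 under quantile normalisation and CPM 2, 21 with the block, 22 with fry, 2 with an estimated correlation and 11 without HEK28 replicates 1 and 2. With 1 library left out 17 to 23 held. Lists in other fits, size factors and a second count model planned for counts were not run.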

Other observations

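The tests against the mean of the other 7 knockouts and all tests along the chromosomes were chosen only after the result was seen; the list tests against HEK28 had been planned.

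Each knockout was set against the mean of the other 7, and since these differences sum to 0 over the 8 lines, a list that is higher in some of them is lower in others by construction. Against HEK28 the p53 list was called higher with CALR, LMAN1 and MCFD2 targeted (adjusted p = 0.0169, 0.0819 and 0.0819 with an estimated correlation) and lower in no knockout. Set against the other 7, p53 targets were higher with CALR targeted (5 of 16 higher and 0 lower, 12 and 0 adjusted over the list alone, median 0.74), with MCFD2 targeted (3 and 0, 7 and 0 over the list alone, median 0.54) and with LMAN1 targeted (1 and 0, 2 and 0 over the list alone, median 0.39). They were lower with ATG7 (0 and 6, 0 and 8 over the list alone, median -0.72), GABARAP (0 and 3, 0 and 7 over the list alone, median -0.56) and GABARAPL1 targeted (0 and 1, 0 and 2 over the list alone, median -0.33). With an estimated correlation the adjusted p was 4.89e-05, 0.00627, 0.0337, 0.000109, 0.000774 and 0.0227 in that order, and that of LMAN1 reached 0.122 without LMAN1 knockout replicate 2. ATF4 targets were higher with CANX targeted (15 and 0 of 33, 30 and 0 over the list alone, median 0.95) and lower with CALR (1 and 7, 2 and 10 over the list alone, median -0.51) and MCFD2 targeted (0 and 6, 1 and 13 over the list alone, median -0.60), at 4.92e-07, 0.0114 and 0.0351, the last 0.0693 without MCFD2 knockout replicate 1. Glycolysis genes (6 and 1 of 21, 11 and 1 over the list alone, median 0.46) were higher with CALR targeted (0.0194). Hypoxia genes were higher with CALR (5 and 0 of 16, 8 and 0 over the list alone, median 0.78) and lower with GABARAP targeted (0 and 6, 0 and 6 over the list alone, median -0.82), both at 0.0489, and 0.117 without CALR knockout replicate 3 and 0.118 without GABARAP knockout replicate 1. Matrix genes were higher with MCFD2 (2 and 0 of 25, 5 and 0 over the list alone, median 0.62, 0.0337) and lower with ATG7 targeted (0 and 1, 0 and 4 over the list alone, median -0.46, 0.0489), reaching 0.0693 without MCFD2 knockout replicate 1 and 0.0946 without ATG7 knockout replicate 1. NRF2 targets were lower with MCFD2 targeted (0 and 3 of 14, 0 and 3 over the list alone, median -0.43, 0.0337, and 0.0735 without MCFD2 knockout replicate 1). These are the 15 of 240 list tests that passed with an estimated correlation, 47 passed with the preset one, and all 15 kept their direction under quantile normalisation and with each library left out.

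The lists of secretory, autophagy and other genes given next passed in no comparison with a wild type by camera, while autophagy receptors passed in the CALR knockout alone (adjusted p = 0.044, or adjusted p = 0.481 with an estimated correlation). For the ATG8 conjugation and autophagy machinery, the lowest adjusted p was 0.734, in the CALR knockout, where 6 of 31 rose and 2 fell. COPII and ER exit genes came to 0.221 with GABARAPL2 targeted, with 7 of 28 higher and 2 lower, and COPI and Golgi genes to 0.107 with ATG7 targeted. ER chaperones and the calnexin cycle reached 0.36 and XBP1 and ATF6 targets 0.247, both in the CALR knockout, where 6 of 23 and 4 of 20 rose and 1 and 0 fell. Genes of ER-associated degradation had a lowest adjusted p of 0.574 and those of ER calcium handling 0.344. Cholesterol synthesis and SREBP2 targets came nearest to the threshold, at 0.0572 with ATG7 targeted, with 7 of 21 higher, 0 lower and a median of 0.81. The interferon list had 6 tested members, of which 0 rose and 3 fell in HEK28 against the parental line (0.146). Of markers of other cell types, the neuronal and adrenal list reached 0.207 and the renal epithelium list 0.276.

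Along the chromosomes, neighbouring genes shifted together in single knockout lines. In windows of 25 genes, each knockout against the mean of the other 7, all 8 lines had stretches of shifted genes, 58 in all. In the GABARAP knockout chromosome 18 was lower from 158383 to 21600884 (47 genes, median -0.80) and from 36187519 to 80247546 (80 genes, median -0.85), the latter with LMAN1 in it, as was chromosome 13 from 26254104 to 114132611 (168 genes, median -0.51). In the CALR knockout it was chromosome 20 from 296968 to 44960486 (177 genes, median -0.52) and chromosome 19 from 2732204 to 14572062 (181 genes, median -0.41), which holds CALR. The CANX knockout had chromosome 5 from 177809407 to 181272307 (32 genes, median -0.85), with CANX in it, chromosome 21 from 37006150 to 46665124 (58 genes, median -0.63), and a higher stretch on chromosome 13 (94 genes, median 0.54). When stretches were found from replicates 1 and 2 alone, 42 came out, and in 41 of them replicate 3 lay on the same side. Stretches held 29.9% of the genes called for CANX against the other 7, 40% for GABARAPL1 and from 1.72% (LMAN1) to 23.2% (GABARAP) in the rest.

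A chance order of the genes does not account for these stretches: in 7 knockouts 0 of 1000 permuted orders reached the highest window median, and in the LMAN1 knockout 9 did. After the trend with the GC content of the 3' ends was removed, 52 of the 58 stretches were found again. A DNA break at the targeted gene does not reach the 51 stretches on other chromosomes without a rearrangement, and it stays open for the 7 on the chromosome of the target, found in 4 knockouts (CANX, CALR, MCFD2 and GABARAPL1). A change in the number of copies of these segments in single clones is a candidate explanation that stays open, as no DNA was measured, and so does any effect of the lost gene itself, since each knockout is 1 line.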
